A study of Homo sapiens with 10 samples.

How the data were processed

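Total RNA from Flp-In T-REx HEK293 cells, a human embryonic kidney line built for doxycycline-controlled expression of an integrated transgene, was measured on 10 one-colour oligonucleotide arrays. Per the labels' protocols, RNA was purified on silica columns with a DNase step, 200 ng of total RNA was converted to biotin-labelled cRNA, the integrated FTO copy was switched on with doxycycline, and siRNAs were delivered by lipofection. The deposited values are probe set signal intensities on a linear scale, made with MAS5 per the submitters' processing notes, which give no version here. The mean of each array's intensities, after 2% of the values were trimmed at each end, was 1000.1 on every deposited array, so each array had been scaled to 1 common level before deposit. That scaling removes any change in the total amount of mRNA per cell, and values are therefore relative to the other transcripts of the same array. The median intensity ran from 123 to 144 over the arrays. An array has no sequencing depth, and the number of arrays limits the precision.

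Of 54675 probe sets, 62 controls were left out of the tests. The annotation table used here paired 41091 probe sets with 1 gene symbol, 1801 with several genes and 11721 with none, and genes were named only from the first kind. Of these, 41037 were matched through their Entrez identifier to a RefSeq gene table, which changed 0 symbols, and 54 kept the symbol of the annotation table. No genome build is named for the arrays, and no coordinates are given.

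Intensities were transformed as log2 of the value plus an offset of 10.23, the 10th percentile of all values, so the fold changes of dim genes are understated. Probe sets with a mean log2 value at or below the median, 7.06 (a signal of 123), were not tested. A gene was represented by its brightest single-symbol probe set, with cross-hybridising sets of the _x_at kind used only where no other was above the filter, which left 12279 genes. Other probe sets above the filter were examined for the named genes, and many of their values are given beside the gene.

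The arrays form 5 groups of 2. In the induction experiment the clones C1 and D4, each carrying the FTO transgene, were measured without induction, at 24 h and at 48 h. In the depletion experiment cells without a transgene were measured 48 h after transfection with FTO siRNA or scrambled siRNA, with numbers 1 and 2 in the labels. The labels do not say whether the siRNA numbers stand for separate cultures, so the spread between these samples may be technical. The p-values there use a spread pooled over all 10 arrays, not that of the siRNA arrays alone. A single limma model (lmFit and eBayes with an intensity trend) was fitted to all 10 arrays with 5 group means and a term for the clone, which left 4 residual degrees of freedom plus 4.73 prior degrees of freedom. Two-sided p-values were adjusted by the Benjamini-Hochberg method over all genes, with a threshold of 0.05. The clone term was part of the design because the labels name the clone of each array. Arrays of 1 clone also deviated together from their group means, with correlations across genes of 0.56 to 0.59. The siRNA number had no term. After the data were examined, the number was found to follow a technical difference between arrays, so depletion values are also given within each number and with the number as a block.

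Gene lists of pathways, complexes and cell type markers, 36 in all, were fixed before the data were examined, as were the comparisons, the alternatives and the rule for named genes. The 34 lists with at least 5 measured members were tested in 4 comparisons with limma's camera at a preset inter-gene correlation of 0.01 and again with an estimated correlation, and p-values were adjusted over the 136 tests. The named genes are, per comparison, up to 12 rising and 12 falling genes past the threshold that moved the same way in both clones or separated the siRNA groups completely. Where fewer than 5 passed in a direction, the list was filled to 5 by smallest unadjusted p among genes that met the same condition. Agreement between the clones is therefore built into the choice of these genes. The FTO probe set, METTL3, METTL14, WTAP, ALKBH5 and up to 4 members of each list that passed, or that held a called gene, were added.

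Simulations with 200 changed genes among 12279 used each gene's real mean and clone difference and its spread pooled over all 10 arrays. The model recovered 57.5% of 2-fold, 93% of 4-fold and 99.6% of 8-fold changes in the 24 h comparison, with 5.35% false calls. At 48 h it recovered 60.4%, 94.2% and 99.6%, with 6.15% false calls. For 48 h against 24 h the shares were 58.6%, 94.6% and 99.4%, and for depletion 61.3%, 94% and 99.2%. These shares hold for 200 changed genes and for the same spread on clone and siRNA arrays. The real clone arrays varied less, with a median residual SD of 0.121 against 0.207 for all 10 arrays. The real siRNA arrays also split by number, which the simulation leaves out. The shares are therefore only a rough guide to the real comparisons. Where few genes change, the adjusted threshold is harder to reach and fewer would be recovered. On the real arrays ADM5, 4.48-fold higher at 24 h, did not pass. The list test found each simulated list of 35 genes shifted by 0.25 in 10 of 10 runs per comparison; the simulated genes were independent of each other.

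The alternatives were another offset or none, quantile normalization, median centring, eBayes without a trend, other filters, the mean of a gene's probe sets, a 2-fold rule without a test, the model with other blocks or with the arrays of 1 experiment, and leaving out each array. Groups of 2 arrays allow no test for outlying arrays. A test of RNA quality on further control transcripts, chosen before its result was seen, is not reported here. The tools were R 4.3.3, limma 3.58.1, Python 3.11.15 and matplotlib 3.10.9.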

Results

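Gene expression was profiled in Flp-In T-REx HEK293 cells, a human embryonic kidney line, with raised, endogenous or lowered levels of FTO. FTO is a 2-oxoglutarate-dependent dioxygenase that removes the methyl group of N6-methyladenosine (m6A) in RNA. The question posed by the design was which transcripts change when FTO is overexpressed or depleted. There were 10 arrays in 5 groups of 2. Noninduced cells, cells induced for 24 h and cells induced for 48 h each came from the transgene clones C1 and D4. Cells without a transgene received FTO siRNA or scrambled siRNA and were collected after 48 h. Doxycycline-treated cells without the FTO transgene were not analysed here, so an effect of doxycycline is part of each induction comparison. Correlations of log2 values between the arrays of 1 group were 0.969 to 0.974.

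FTO itself followed the labels on every array. Its only probe set read 5694 ± 217 (SD, n = 2) in noninduced clones, 35203 ± 539 (SD, n = 2) after 24 h and 37346 ± 4232 (SD, n = 2) after 48 h of doxycycline. It read 3100 ± 353 (SD, n = 2) after scrambled siRNA and 622 ± 135 (SD, n = 2) after FTO siRNA. FTO rose 6.17-fold at 24 h (log2 2.63, SE 0.17, limma adjusted p = 0.00122) and 6.53-fold at 48 h (log2 2.71, SE 0.17, adjusted p = 0.000941), and was 4.96-fold lower after FTO siRNA (log2 -2.31, SE 0.17, adjusted p = 0.00358). Between 24 h and 48 h it differed by 0.08 (SE 0.17), within the replicate error. Without doxycycline the clones gave a value 1.84-fold that of scrambled siRNA cells (log2 0.88, SE 0.17, limma unadjusted p = 0.000547). The difference did not pass when adjusted over all genes (adjusted p = 0.244), so a higher FTO level in the noninduced clones stays open. The clones and the transfection differ between these cells, and the cause was not tested. The induced gain did not pass without any 1 of the 4 arrays compared at 24 h (adjusted p = 0.0673 to 0.118), nor at 48 h without noninduced C1, noninduced D4 or 48 h D4 (adjusted p = 0.0547, 0.0926 and 0.0956). The loss after siRNA did not pass without the intensity trend (adjusted p = 0.101) or in a fit of the 4 siRNA arrays alone (adjusted p = 0.558).

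**Figure D1:**
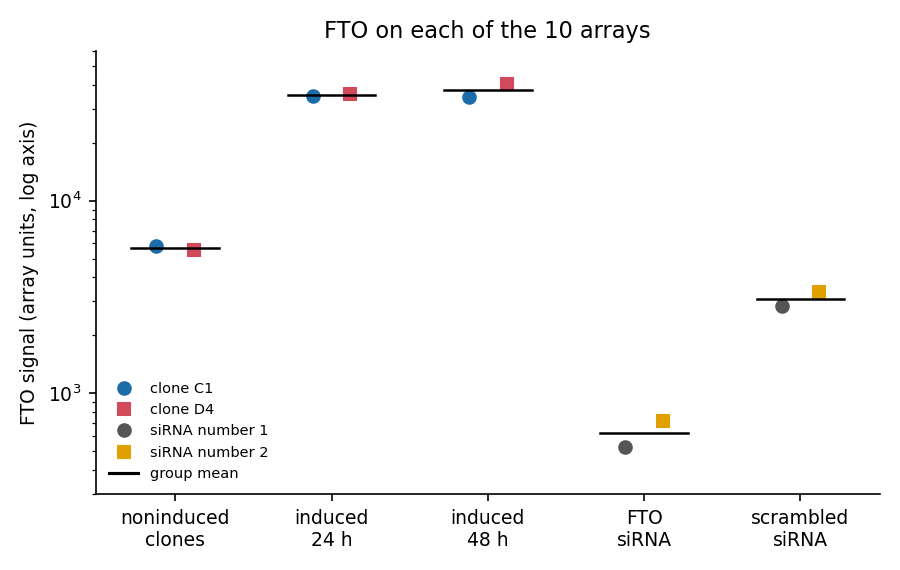
FTO signal in array units on a log axis for each of the 10 arrays, by group; circles are clone C1 or siRNA number 1, squares clone D4 or number 2, and bars group means. The 4 induced arrays lie between 34354 and 40338, above noninduced arrays at 5541 and 5848, and the FTO siRNA arrays at 527 and 717 lie below the scrambled arrays at 2851 and 3350.

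After 24 h of induction FTO was the only gene among 12279 that passed the test. At an unadjusted p under 0.05 there were 112 genes, 0.912% of those tested. The spread pooled over the 10 arrays (median residual SD 0.207) includes a split of the siRNA arrays described below. It exceeds that of the 6 clone arrays (0.121), which makes the induction tests conservative. The depletion tests use the same pooled spread, which the clone arrays lower and the split of the siRNA arrays raises. That split falls on FTO siRNA and scrambled arrays alike, so it widens the error of their difference. At an unadjusted p under 0.05 the depletion comparison held 2.91% of genes, so its tests were not lenient across genes as a whole. A fit of the clone arrays alone also called 1 gene, FTO (SE 0.09, adjusted p = 1.62e-07). In that fit 511 genes, 4.16% of those tested, had an unadjusted p under 0.05. A share of about 0.05 is reached without any change. Of the m6A machinery list, 19 of 20 measured members did not pass, FTO being the exception. The methyltransferase subunits METTL3 and METTL14 stood at log2 -0.05 (SE 0.13) and -0.02 (SE 0.15), their partner WTAP at -0.05 (SE 0.13), and ALKBH5, the other m6A demethylase, at 0.08 (SE 0.13). Of the m6A-binding proteins in that list, IGF2BP2 stood at -0.19 (SE 0.12) and IGF2BP3 at -0.15 (SE 0.16). Other METTL3 probe sets stood at 0.28 (SE 0.22) and 0.36 (SE 0.33). In the AlkB family list, of related dioxygenases, the 8 members other than FTO did not pass, with ALKBH6 at 0.12 (SE 0.13) and ALKBH2 at -0.12 (SE 0.15). Among genes that moved the same way in both clones, those with the smallest unadjusted p in each direction did not pass (adjusted p = 0.9999) and had these values. ADM5, a gene related to adrenomedullin, stood at 2.16 (SE 0.35; signal 232 against 43.9, the lower level being below the filter), the growth factor gene VEGFB at 1.09 (SE 0.27), ZNF579 at 1.27 (SE 0.32) and UNKL at 0.61 (SE 0.15). The dopamine transporter gene SLC6A3 stood at -1.21 (SE 0.34), the golgin gene TRIP11 at -0.77 (SE 0.21), SLX9 at -0.97 (SE 0.28), FAM86B2-DT at -0.71 (SE 0.20) and RAI1 at -0.44 (SE 0.12). Other probe sets above the filter stood at -0.31 for UNKL, -0.13 for SLX9, -0.18, -0.25 and 0.19 for TRIP11 and 0.06 for RAI1. By size alone, 9 genes differed at least 2-fold the same way in both clones, 8 higher and 1 lower, and 9 others differed as much in opposite directions. None of the 34 lists passed at 24 h. The smallest adjusted p, 0.0752, was that of the metallothionein list, with a mean of 0.18. The amino acid response list holds 35 measured genes, ATF4 itself and mainly genes that it induces when amino acids are short. The list's mean was -0.08, with 10 members above 0 and 25 below (camera adjusted p = 0.324).

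After 48 h FTO was again the only gene called, with 146 genes (1.19%) at an unadjusted p under 0.05. The fit of the clone arrays alone called FTO as well, with 734 genes (5.98%) at an unadjusted p under 0.05. The amino acid response list rose by a mean of 0.15, with 30 members above 0 and 5 below (camera adjusted p = 0.000456). It was not called with an estimated correlation (adjusted p = 0.9994, unadjusted p = 0.115). None of its members passed singly or when adjusted over the list alone (0 of 35). The cystine transporter gene SLC7A11 stood at 0.34 (SE 0.14), asparagine synthetase ASNS at 0.34 (SE 0.15), the stress transcription factor gene DDIT3 at 0.37 (SE 0.17) and the tRNA exporter gene XPOT at 0.20 (SE 0.10), with further probe sets at -0.03 and 0.37 for SLC7A11 and 0.05 for XPOT. The list's mean was 0.02 in C1 and 0.27 in D4, and the call was lost without the noninduced D4 array (0.06) or the 48 h D4 array (0.05), and with no filter on dim probe sets (adjusted p = 0.0760). On the same arrays the beta-actin 3'/5' signal ratio was 1.76 in C1 and 1.503 in D4 at 48 h, against 1.28 and 1.37 without induction.

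Other lists at 48 h did not pass. Cytosolic ribosomal protein genes had a mean of 0.10, with 31 of 33 above 0 (adjusted p = 0.0810), and genes of the mitochondrial ribosome and translation a mean of -0.06, with 46 of 57 below 0 (adjusted p = 0.0810). The m6A core genes were near 0 again, with METTL3 at -0.07 (SE 0.13), METTL14 at 0.01 (SE 0.15), WTAP at 0.00 (SE 0.13) and ALKBH5 at 0.13 (SE 0.13). Within the m6A list the writer-complex genes RBM15, CBLL1 and RBM15B stood at 0.19, 0.29 and -0.23, with other RBM15 probe sets between -0.20 and 0.34, and in the AlkB family ALKBH1 and ALKBH8 at -0.12 and -0.13. Genes named without passing (adjusted p = 0.9999) were ADM5 at 1.87 (SE 0.35), the cornified envelope gene SPRR4 at 1.45 (SE 0.33), the helicase gene HELZ2 at 1.48 (SE 0.38; its noninduced level below the filter) and the deubiquitinase gene OTUB2 at 0.83 (SE 0.22). On the lower side were GGCX, the vitamin K-dependent carboxylase, at -0.83 (SE 0.23), the anaphase-promoting complex activator FZR1 at -0.93 (SE 0.28), APOL2 at -0.67 (SE 0.22), arginyl-tRNA synthetase RARS1 at -0.57 (SE 0.19) and N-acetylaspartate synthetase NAT8L at -0.49 (SE 0.17). Other probe sets stood at -0.70, -0.09, 0.03 and 0.06 for GGCX, at -0.27, 0.33 and 0.33 for FZR1, at 0.31 for HELZ2, at 0.17 for OTUB2 and at 0.28 and 0.52 for METTL3. The 2-fold rule gave 8 genes, 7 higher and 1 lower, with 5 more in opposite directions in the clones.

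Between 24 h and 48 h of induction 0 genes passed in limma's test, with 157 (1.28%) at an unadjusted p under 0.05. The 2-fold rule gave 9, 7 higher and 2 lower, with 13 more in opposite directions in the clones. The fit of the clone arrays alone also called 0, with 1062 (8.65%) at an unadjusted p under 0.05. The amino acid response list rose by a mean of 0.22, with 31 of 35 members above 0 (camera adjusted p = 7.5e-07). It was not called with an estimated correlation (adjusted p = 0.9994, unadjusted p = 0.0569). The mean was 0.14 in C1 and 0.30 in D4. ASNS stood at 0.43 (SE 0.15), the glutathione-degrading enzyme gene CHAC1 at 0.66 (SE 0.23), XPOT at 0.27 (SE 0.10) and SLC7A11 at 0.30 (SE 0.14), and 0 of 35 passed singly. Further probe sets stood at 0.00 and 0.44 for SLC7A11 and 0.08 for XPOT. Without the 48 h D4 array the list's mean was 0.12 and it did not pass (adjusted p = 0.297). The beta-actin 3'/5' log2 ratio was higher at 48 h than at 24 h by 0.32 in C1 and 0.11 in D4, and that of the spiked-in Dap transcript by 0.61 and 0.10.

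The metallothionein list, 6 genes of these zinc- and copper-binding proteins plus the zinc exporter SLC30A1, fell by 0.33 between 24 h and 48 h, with 7 of 7 members below 0 by the probe sets that stood for them (camera adjusted p = 0.000378; with an estimated correlation adjusted p = 0.9994, unadjusted p = 0.0398). MT1X stood at -0.46 (SE 0.17), MT1H at -0.59 (SE 0.25), MT1F at -0.44 (SE 0.22) and MT2A at -0.18 (SE 0.14), with 0 of 7 past the threshold. A further MT1F probe set stood the other way, at 0.35 (SE 0.24), and a further MT1X set at -0.36 (SE 0.21). The 6 metallothionein genes were read by probe sets that cross-hybridise within the family, so they are not independent of each other. The mean was -0.12 in C1 and -0.54 in D4. The call was lost without the 24 h D4 array (-0.19), without the 48 h D4 array (-0.16) and with no filter (adjusted p = 0.0574). The Wnt target list (mean 0.24, 9 of 9 above 0, adjusted p = 0.0752) and the mitochondrial ribosome list (mean -0.07, 46 of 57 below 0, adjusted p = 0.0602) did not pass.

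Single genes named for 48 h against 24 h did not pass either (adjusted p = 0.9998). CCDC106 stood at 1.53 (SE 0.34; its 24 h level below the filter), the cysteine desulfurase gene NFS1 at 0.62 (SE 0.14), RAI1 at 0.50 (SE 0.12), SPRR4 at 1.36 (SE 0.33) and COQ8B, of coenzyme Q synthesis, at 0.78 (SE 0.20). DEPDC1B stood at -0.74 (SE 0.16), the centrosomal gene CEP162 at -0.94 (SE 0.23), the co-chaperone gene BAG1 at -0.57 (SE 0.15), mitochondrial tyrosyl-tRNA synthetase YARS2 at -0.77 (SE 0.23) and NAP1L2 at -0.88 (SE 0.27). A further CEP162 probe set stood at -0.07, a further NFS1 probe set at 0.13, a further RAI1 set at 0.00 and further BAG1 sets at -0.43 and -0.20. METTL3, METTL14, WTAP and ALKBH5 lay between -0.02 and 0.05.

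**Figure D2:**
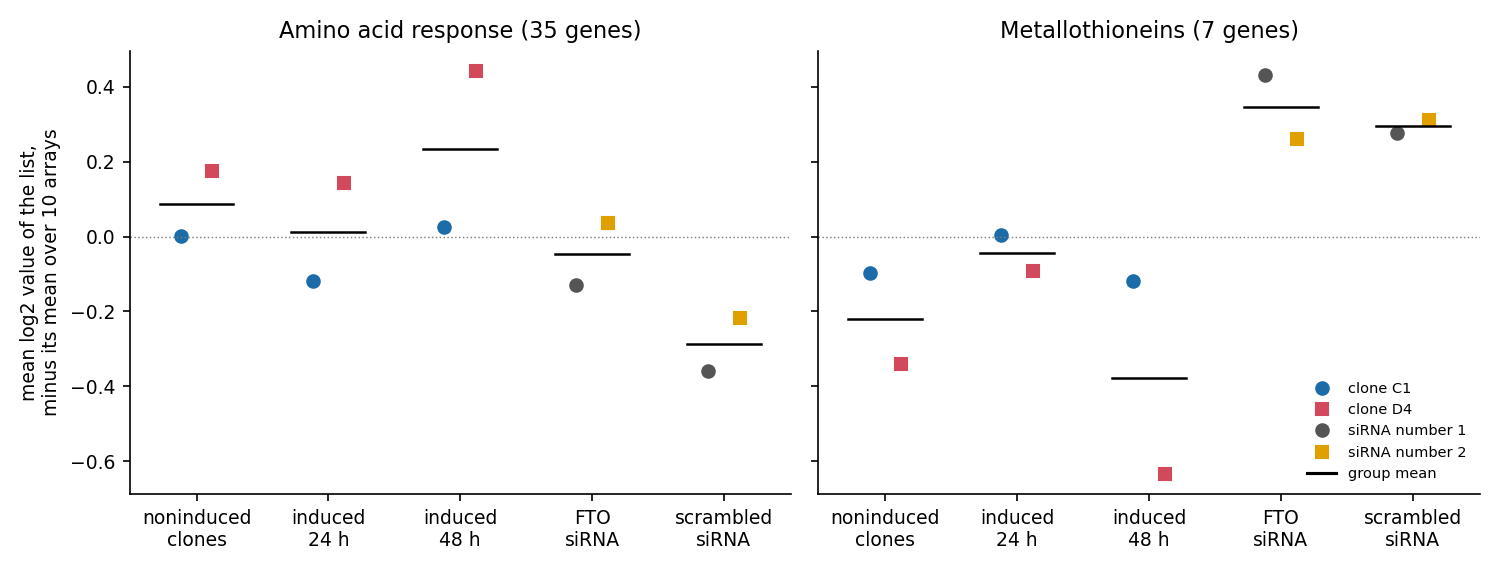
Mean log2 value of the amino acid response list (left) and the metallothionein list (right) on each of the 10 arrays, minus the list's mean over the arrays; circles are clone C1 or siRNA number 1, squares clone D4 or number 2, and bars group means. The amino acid response list is higher in each FTO siRNA array (-0.13 and 0.04) than in the scrambled array of the same number (-0.36 and -0.22), and its highest array is 48 h D4 at 0.44.

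The changes at 24 h and 48 h were correlated across genes (r = 0.438, where genes are not independent replicates), but both comparisons use the same noninduced arrays. Simulated groups without any change gave 0.4998 on average (lowest 0.477, highest 0.523 of 100 simulations), above the observed value. The observed covariance was 0.0216. Simulations gave 0.0360 with the spread pooled over the 10 arrays and 0.0193 with that of the clone arrays alone (lowest 0.0183, highest 0.0207), so the observed value lay below the first simulations and above the highest of the second. Between the clones, which share no arrays, the 48 h changes correlated at 0.0312 and the 24 h changes at 0.0257.

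After FTO depletion FTO was the only gene of 12279 called in the model without the siRNA number. There were 357 genes (2.91%) at an unadjusted p under 0.05. By size, 7 genes, 2 higher and 5 lower, differed at least 2-fold between each FTO siRNA array and each scrambled array. Next came COPS8, which encodes a subunit of the COP9 signalosome, at 2.04-fold lower (log2 -1.03, SE 0.12, adjusted p = 0.0657), and LIN28B, an RNA-binding protein that blocks let-7 maturation, at 1.92-fold lower (log2 -0.94, SE 0.13, adjusted p = 0.232). COPS8 passed after quantile normalization (adjusted p = 0.0421) and with the stricter filter (adjusted p = 0.0435). Its other 4 probe sets above the filter stood at -0.86, -0.42, -0.88 and -0.79. The G protein subunit gene GNG12 stood at -0.77 (SE 0.14), with its other probe sets at -1.05 and -0.997, and FAM241A at -0.61 (SE 0.14). On the higher side were NAT8L at 0.89 (SE 0.17), the transcription factor gene USF2 at 0.83 (SE 0.16), EFR3A at 0.75 (SE 0.16), SLC7A11 at 0.69 (SE 0.14) and the eEF1A methyltransferase gene EEF1AKMT1 at 0.58 (SE 0.12), none of which passed (adjusted p = 0.9993). Further probe sets stood at 0.13 for NAT8L and at -0.11 and 0.46 for USF2, and those of EFR3A (0.75) and SLC7A11 (0.61 and 0.54) lay close to it.

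The siRNA arrays differed by number on the technical controls. The beta-actin 3'/5' ratio was 1.58 and 1.56 on the FTO siRNA and scrambled arrays numbered 1, and 3.36 and 3.33 on those numbered 2, against 1.28 to 1.76 on the clone arrays. Deviations of same-numbered siRNA arrays from their group means correlated at 0.602 across genes. When the 4 arrays were split by number, 160 genes differed at least 2-fold, against 7 for FTO siRNA against scrambled siRNA and 4 for the remaining split. With the number as a block, a fit chosen for emphasis after this difference was seen, 18 genes passed, 9 higher and 9 lower. At an unadjusted p under 0.05 there were 1236 of 12279 genes with the block, against 357 without it. Such a fit favours genes whose 2 pairs are alike. Its spread, with 3 residual degrees of freedom, is again pooled with the clone arrays. It therefore also favours genes with little residual spread in the clones. Of the 18 genes, those outside the named genes above are given after their values were seen.

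Under that block COPS8 fell by 1.03 (SE 0.09, adjusted p = 0.00063; -1.12 in number 1 and -0.95 in number 2) and LIN28B fell by 0.94 (SE 0.08, adjusted p = 0.00063; -0.96 and -0.92). GNG12 (-0.77, SE 0.11), FAM241A (-0.61, SE 0.10), the LRP5/6 chaperone gene MESD (-0.62, SE 0.09), AGGF1 (-0.61, SE 0.09), the sorting nexin gene SNX10 (-0.60, SE 0.10) and NPC2, which carries cholesterol in lysosomes (-0.52, SE 0.08), fell as well. Among the genes that rose, DEPP1, a FOXO-responsive gene, was higher by 2.09 (SE 0.30; 2.43 and 1.75 in the numbers), with its scrambled level below the filter. The others were NAT8L (0.89, SE 0.12), USF2 (0.83, SE 0.13), EFR3A (0.75, SE 0.11), SLC7A11 (0.69, SE 0.11), the arrestin-family gene ARRDC4 (0.67, SE 0.09), EEF1AKMT1 (0.58, SE 0.09), argininosuccinate synthase ASS1 (0.56, SE 0.09) and the microtubule end-binding gene MAPRE1 (0.53, SE 0.09). Adjusted p-values of the 15 genes other than FTO, COPS8 and LIN28B lay between 0.0381 and 0.0465. FTO fell by 2.31 (SE 0.10, adjusted p = 7.8e-07), with -2.41 in number 1 and -2.21 in number 2.

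**Figure D3:**
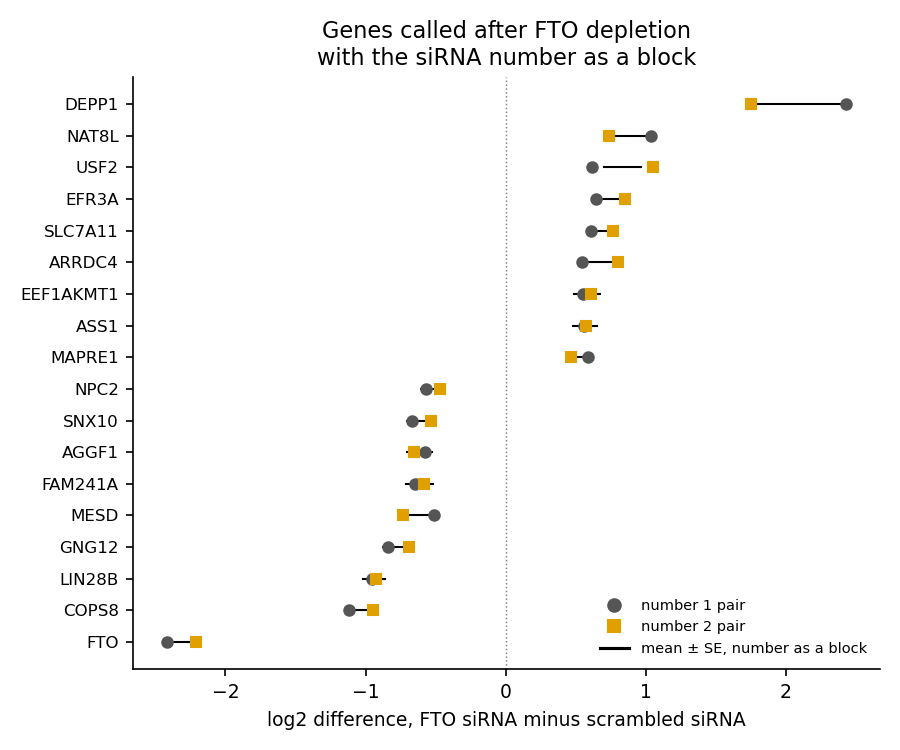
Log2 difference between FTO siRNA and scrambled siRNA for the 18 genes called with the siRNA number as a block; circles are the number 1 pair of arrays, squares the number 2 pair, and lines the mean ± SE. The means run from DEPP1 at 2.09 to FTO at -2.31, and the fit that chose the genes favours pairs that are alike.

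As a group, amino acid response genes rose after FTO depletion, by a mean of 0.24 with 32 of 35 members above 0 (camera adjusted p = 7.5e-07). The list was not called with an estimated correlation (adjusted p = 0.9994, unadjusted p = 0.0576). The mean was 0.23 within number 1 and 0.25 within number 2, and with the number as a block the list passed at the preset correlation (adjusted p = 1.59e-07 over the 34 lists) and not with an estimated one (adjusted p = 0.889). Adjusted over the list alone, 1 of 35 members passed, SLC7A11. The serine synthesis genes PSAT1 and PHGDH stood at 0.48 (SE 0.12) and 0.37 (SE 0.13), and ASNS at 0.44 (SE 0.15). Leaving out single siRNA arrays moved the list's mean between 0.16 and 0.32. In the m6A machinery list 19 of 20 measured members did not pass, FTO again being the exception. METTL3 stood at 0.06 (SE 0.13), METTL14 at -0.15 (SE 0.15), WTAP at 0.02 (SE 0.13), ALKBH5 at 0.09 (SE 0.13), IGF2BP2 at 0.29 (SE 0.12), IGF2BP1 at -0.42 (SE 0.29) and RBM15B at -0.21 (SE 0.18). Other probe sets stood at -0.76 (SE 0.42) for IGF2BP2, at 0.21 (SE 0.34) and 0.00 (SE 0.40) for IGF2BP1 and at 0.12 (SE 0.23) and -0.13 (SE 0.21) for METTL14. In the AlkB family ALKBH2 stood at 0.21 (SE 0.15) and ALKBH7 at -0.12 (SE 0.16; another probe set 0.14), and neither passed. The interferon-stimulated list, which could respond to transfected RNA, had a mean of 0.12 with 16 of 22 members above 0 and did not pass (adjusted p = 0.352), nor did the endoplasmic reticulum unfolded protein response (mean 0.11, adjusted p = 0.324).

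The direct test of 48 h induction against depletion called FTO alone (difference 5.02, SE 0.23, adjusted p = 9.34e-05), with 216 genes (1.76%) at an unadjusted p under 0.05. The clones, doxycycline and transfection differ between these experiments too. With the siRNA number as a block 5 genes passed, namely FTO, COPS8 (0.95), LIN28B (0.82), CCDC152 (1.27) and NAT8L (-1.38). COPS8 and LIN28B moved little at 48 h of induction (-0.08 and -0.12), so their difference mainly repeats the depletion change. NAT8L stood at 0.89 after depletion and at -0.49 at 48 h. Across genes the 48 h and depletion changes were not correlated (r = -0.00718), with 49.4% of genes changing in the same direction. The 24 h and depletion changes gave r = -0.0618, with 47.3% in the same direction. Since the 48 h changes of the clones correlated at only 0.0312 with each other, a relation with depletion could hardly appear. These correlations therefore do not decide whether there is one. Means of the amino acid response list were -0.08 at 24 h and 0.15 at 48 h of induction, and 0.24 after depletion.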

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

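The matched-list tests below were chosen before their result was seen; the tests of RNA quality on these lists, of spread between cultures and of the spiked-in controls were chosen afterwards. A closer look was prompted by lists and genes whose response differed between 24 h and 48 h of induction.

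The amino acid response list differed between 24 h and 48 h by 0.22. The test of the difference itself did not pass with an estimated correlation (camera adjusted p = 0.9994). Part of the difference was the list's 24 h mean of -0.08, above only 0.53% of matched lists. Leaving out single arrays moved that mean between -0.16 and 0.01. A bias that follows signal level is argued against, since the difference lay above those of 100% of 10000 random lists matched on size and mean signal. The beta-actin 3'/5' log2 ratio rose by 0.3225 in C1, where the list moved less, and by only 0.11 in D4, where it moved more. That order runs against lower RNA integrity at 48 h as the explanation, but single pairs of arrays do not settle it. The spiked-in Dap and Thr ratios, which cell RNA does not set, also rose in C1 (0.61 and 0.34) and moved by 0.10 and -0.29 in D4, so a labelling difference stays open as well. Fluctuation of a co-regulated list between cultures may account for it: the shift was 2.247 times the residual standard error of the list's mean, which 4 degrees of freedom do not separate from 0, while a response to 48 h of FTO or of doxycycline stays open and was not tested.

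After FTO depletion the same list was higher by 0.24 (not called with an estimated correlation, adjusted p = 0.9994), above 100% of the matched lists, which argues against a signal-level bias. Lower RNA integrity in the FTO siRNA cultures is argued against, since the beta-actin log2 ratio differed from that of the scrambled array of the same number by at most 0.0218. The spiked-in ratios differed by 0.03 and 0.20 in the 2 numbers for Dap, 0.04 and -0.35 for Thr, 0.12 and 0.38 for Phe and 0.92 and 0.39 for Lys, so a labelling difference stays open. Fluctuation between cultures stays open: the shift was 2.441 residual standard errors without the siRNA number, short of the two-sided threshold, and 3.361 with it, past the threshold. The higher list at 48 h of induction (0.02 in C1, 0.27 in D4), though not at 24 h, and after depletion could reflect culture conditions such as medium use, a possible explanation that these arrays do not test.

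The split of the siRNA arrays by number is consistent with a difference at labelling. The 3'/5' log2 ratio of the bacterial Dap and Thr transcripts, which are usually spiked into RNA before labelling, was higher in number 2 by at least 1.235 in both siRNA groups. The weaker spiked-in transcripts did not all show it: Phe differed by 0.69 and 0.42, and Lys by -0.38 and 0.16, while GAPDH differed by 0.12 and 0.11. Degraded cell RNA alone is argued against, since spiked-in RNA would then not differ, whereas its difference reached 2.016. Hybridization controls in number 2 read 0.664 of their level on the other 8 arrays.

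The metallothionein list also differed between 24 h and 48 h, with a mean of -0.33 by a test of the difference. It did not pass with an estimated correlation (adjusted p = 0.9994), or without the 24 h D4 array (-0.19) or the 48 h D4 array (-0.16). Several named genes stood on 1 side of the noninduced level in both clones at 24 h and on the other side in both at 48 h, although none passed the test of the difference (adjusted p = 0.9998). The 48 h value exceeded the 24 h value for CCDC106 by 1.53, COQ8B by 0.78, CHAC1 by 0.66, NFS1 by 0.62, RAI1 by 0.50, ASNS by 0.43, XPOT by 0.27 and ALKBH2 by 0.14. The 48 h minus 24 h value was -0.88 for NAP1L2, -0.77 for YARS2, -0.74 for DEPDC1B, -0.61 for RARS1, -0.57 for BAG1 and -0.46 for MT1X. Most of these genes were named for their 48 h against 24 h difference, so that such a turn is common among them.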

How the results depend on the processing

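Alternatives marked here as added were chosen after seeing the data. FTO kept its direction in each setting run. Leaving out 1 array at a time put its log2 change at 2.52 to 2.73 at 24 h, 2.58 to 2.83 at 48 h and -2.53 to -2.09 after depletion; with fewer arrays the call ended without any of the 4 at 24 h and without 3 of the 4 at 48 h. After depletion the value of -2.31 did not pass without the eBayes trend or in the fit of the same experiment. Where 1 array of a group is left, it is assumed to vary like the other groups. The number of genes called was 0 in each leave-one-out fit at 24 h, 0 to 1 at 48 h and 1 to 2 after depletion. For 48 h, the arrays of clone D4 alone or of clone C1 alone (added) gave 0. For depletion, 0 genes were called without the trend and in the fit of the same experiment, 2 after quantile normalization, 2 with the stricter filter, 6 with the siRNA arrays numbered 1 alone (added), a pair without replicates, and 18 with the replicate block; 5 genes passed with the replicate block in the test of induction against depletion. The 2-fold rule gave 9 genes at 24 h, 8 at 48 h, 9 between them and 7 after depletion. Without the clone as a replicate block FTO stayed the 1 gene called at 24 h and at 48 h.

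The amino acid response list at 24 h, which did not pass in the model as designed, passed without noninduced D4 (-0.16, adjusted p = 0.0103) and moved to 0.01 without noninduced C1.

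Of 136 list tests, 4 passed in the model as designed, 3 of the amino acid response list and 1 of the metallothionein list; 2 passed with no filter and 0 with an estimated correlation. The correlation of 24 h and 48 h changes was 0.503 with no filter. The relation of induction and depletion effects kept within its spread in each of 3 alternatives. For these results the cause was not tested, apart from the fewer arrays of the leave-one-out fits. The 2-fold rule and the fit of 1 experiment were not run for the test of induction against depletion. Dim genes could not be seen, since probe sets under a signal of 123 were left out. Sensitivity was limited among the tested genes too, with 57.5% of simulated 2-fold changes recovered at 24 h.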

Other observations

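The tests in this part were chosen after the data had been seen. The arrays of clone C1 and those of clone D4 differed far more than either clone changed on induction. C1 is number 1 and D4 number 2 in the labels throughout, so a batch shared by all arrays of a number would be confounded with the clone. The clone term of the model called 766 genes, 393 higher in C1 and 373 higher in D4, and a fit of the 6 clone arrays alone called 3728, among them the 766. SLITRK5, a neuronal membrane protein gene, was higher in D4 (C1 minus D4 -5.43, SE 0.24), as were the cell adhesion gene LSAMP (-3.99, SE 0.54), the actin-bundling gene LCP1 (11.7-fold; -3.55, SE 0.19) and the endothelin receptor gene EDNRB (-3.11, SE 0.37). The neural transcription factor gene ZIC1 (-2.91, SE 0.24) and the glucocorticoid-responsive gene TSC22D3 (-2.37, SE 0.32) were also higher in D4. In C1 the zinc finger gene ZNF22 was higher (3.74, SE 0.23), annexin ANXA1 6.93-fold (2.79, SE 0.16) and neurotensin NTS 5.72-fold (2.52, SE 0.18). The lower level of SLITRK5, LSAMP, EDNRB, ZIC1 and ZNF22 was below the filter, so the offset affects their differences and no fold is given. The siRNA arrays, which carry no clone, also split by number, partly in the same way. Of the 3728 genes, 67.5% had the same direction in number 1 minus number 2 of the siRNA arrays as in C1 minus D4 (r = 0.399, slope 0.292), against 59.7% of all genes (r = 0.267). Among the genes named here the siRNA difference was -0.26 for SLITRK5, 0.21 for LCP1, 0.40 for ZNF22, -0.22 for ANXA1 and -0.26 for NTS, but -0.92 for LSAMP, -1.06 for EDNRB and -1.10 for TSC22D3. FTO itself did not pass between the clones (-0.06, SE 0.14). The 10 splits of the 6 clone arrays into 3 and 3 are too few for a share under 0.05; 1 split, that by clone, called as many as 766 genes, and the highest of the others called 0.

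Among the fixed lists, 5 of 34 passed between the clones at the preset correlation, and 0 with an estimated correlation (adjusted p = 0.724 for each of the 5). The list of genes near FTO on chromosome 16, 6 measured, was higher in C1 by a mean of 0.50 (adjusted p = 0.00219). CHD9 (0.78) and AKTIP (0.57) were called, while IRX5 (0.63), RPGRIP1L (0.52), RBL2 (0.26) and IRX3 (0.25) were not. The endoplasmic reticulum unfolded protein response was higher in C1 by 0.25 (adjusted p = 0.0114), with HSPA5 (0.85), MANF (0.64) and PDIA4 (0.58) called, and was also higher by 0.20 in number 1 than in number 2 of the siRNA arrays. Amino acid response genes were higher in D4 (mean -0.28, adjusted p = 0.00503), with DDIT3 (-1.15), TXNIP (-1.53) and ASNS (-0.70) among 6 called in that direction, and SLC7A5 (1.09) the other way; the siRNA difference was -0.15. Hypoxia genes were higher in D4 (-0.42, adjusted p = 0.0252), but the siRNA arrays had a difference of -0.52 between the numbers, so this shift is not particular to the clones. G2/M genes were higher in D4 (-0.18, adjusted p = 0.0135), with -0.03 in the siRNA arrays, and the genes near FTO had -0.10 there.

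A hypothesis was that genes changed by FTO siRNA follow the FTO level both down and up. The 17 genes other than FTO called with the number as a block changed by a mean of 0.782 in size after depletion. At 48 h of induction, on arrays that entered the choice of genes only through the pooled spread, 8 of 17 stood opposite to their depletion change, and the mean opposing movement was 0.00294 (SE across genes 0.0508). The set as a whole thus gave no sign of a graded response in both directions. Genes read on the same arrays are not independent replicates, so the SE across genes may be too small. The mean of 0.782 comes from genes chosen for passing, so it may be too large. A response that saturates at the endogenous FTO level, an effect of the siRNA on other transcripts, and the different cells used remain possible and were not tested.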
